A study of Pan troglodytes
Homo sapiens and Pongo abelii
Homo sapiens and Pan troglodytes with 21 samples.

How the data were processed

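RNA was measured in 21 samples of pluripotent stem cells in 7 groups of 3. Human cells had been fused with chimpanzee or orangutan cells, and each of these composite lines carried mitochondrial DNA (mtDNA) of 1 of its contributors. Sample titles call the composite samples tetraploid and give no ploidy for the contributor lines. Contributor lines were a human embryonic stem cell line whose name was not given, chimpanzee induced pluripotent stem cells and orangutan induced pluripotent stem cells. Per the labels' protocols, cells were grown in mTeSR Plus on Matrigel and lysed at about 70% confluency, RNA was taken with the RNeasy Mini Plus kit, and libraries were made with the SMARTer mRNA-Seq kit. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. In HO_human_mt, a human-orangutan group, the median chromosome 12 shift (log2) was 0.23, 0.18 and -0.11 in replicates 1, 2 and 3. This argues against 3 libraries of 1 RNA sample in that group, and for the other groups the question stays open. Nor do they say how many fused lines carried each mtDNA, so mtDNA type cannot be separated from line or culture.

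The authors deposited 7 tables of estimated counts per gene, as whole numbers and not normalized, and 33 columns were read, with 0 columns left unused. Each fusion has a table against the human genome and a table against its ape genome, and each contributor line has a table against its own. Per the submitters' processing notes, HISAT2 2.1.0, StringTie 2.1.7 and Trim Galore 0.6.10 were used, and GRCh38 and GRCm39 were listed as builds. Roles of these tools, the reason for the mouse build and the ape builds are not given in the sources used here. Whether counting used strand is not given either, so overlapping and antisense genes cannot be separated.

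Whether the tables of a fusion split reads by allele is not given in the sources used here. In the human-chimpanzee (HC) fusion 60.5% of 10164 shared symbols had counts within 10% of each other in the human and chimpanzee tables, and in the human-orangutan (HO) fusion 48.3% of 9731 did. ACTB, for example, had 638501 and 637180 counts in the human and chimpanzee tables of HC_human_mt replicate 1, and TFAM had 8137 and 8079. Many reads may thus be counted in both tables, and the composite tables may hold reads of both species. Tables split by allele could give similar counts too where both genomes are expressed alike, so this was not settled. Genes of mtDNA were kept apart, at 3.92% of human-table and 0.0327% of chimpanzee-table counts in HC_human_mt. Both tables of a fusion come from the same libraries and are not independent. Possible sharing of reads limits every value that adds or divides the tables. It also confounds comparisons with contributor lines, whose tables hold 1 species and were counted separately.

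Counts were tested as deposited, and since they were whole numbers no rounding was needed. Differences between groups were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the edgeR expression filter by group and Benjamini-Hochberg adjustment at 0.05, two-sided. Standard errors are the absolute log2 change divided by the square root of F. Genes of mtDNA, found by symbol, were left out of the scaling and tests of single tables and kept in the tests of summed tables. Unnamed mtDNA genes of the ape tables could not be left out this way. Main comparisons set ape against human mtDNA within each fusion and table. Others were the sum of both tables per symbol, the difference between the fusions' mtDNA effects (an interaction term), the change of the human-to-ape table ratio with mtDNA, and each composite against the contributor of its mtDNA. CPM values are after TMM scaling, and nuclear copies of mtDNA were recognised by symbol.

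In all, 33 gene lists with 811 entries were fixed, covering respiration, mitochondrial upkeep, metabolism, stress, cell division, pluripotency, lineage markers and gene families. A list was tested with limma 3.58.1 where at least 3 members were tested, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, on log2 CPM with a prior count of 2. No list call by camera held with an estimated correlation in any comparison. That test did not call the mtDNA-encoded protein genes of the summed tables either, although DESeq2 called each of them lower with ape mtDNA. A missing call by it therefore does not show that a list is unchanged. Calls with the preset correlation remain without support from it. Differences in the share of counts from mtDNA-encoded protein genes used a two-sided exact permutation test, adjusted over 8 tests, in which 3 against 3 libraries cannot give a p below 0.10.

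Named genes followed a rule. For main comparisons these were the 5 highest and 5 lowest changes among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap, then the called member of each list with the smallest p in each direction, with the next 2 for up to 6 leading lists. For other comparisons the 3 highest and 3 lowest and the leading member of up to 4 lists were taken. POU5F1, NANOG, SOX2, TFAM and the mtDNA-encoded protein genes were always included, and Y-linked genes, XIST, TSIX and clone names never. For the interaction the requirement that groups do not overlap was not applied. Coordinates came from GENCODE 29 on GRCh38 by Ensembl identifier, which covered 78 of 79 named entries of the human tables, and ape genes were placed by the chromosome of their human namesake.

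Groups, tests, lists, the naming rule and a set of other settings were fixed before the data were examined. These settings were DESeq2 size factors, the DESeq2 1.42.0 test, no expression filter, each library left out in turn, the replicate number as a block, mtDNA genes kept in or left out, all composite libraries fitted together, and symbols of both tables only. Leaving out nuclear copies of mtDNA, leaving out 4 chromosomes and removing chromosome shifts were added after seeing the data.

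The test was checked on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes, of which 67 were changed 2-fold. Of those 67 edgeR recovered 65.7% in the HC human table, 92.5% in the HC chimpanzee table, 32.8% in the HO human table, 52.2% in the HO orangutan table and 23.9% for the interaction. It called 10 of 22358 unchanged genes in the first of these. By camera with the preset correlation, a simulated shift was found in 13 of 13 changed lists, and 0 unchanged lists had a p under 0.05. Simulated genes were drawn independently of each other, so this cannot show how often real lists, whose members may vary together, are called falsely. Replicates were compared in 33 pairs, and chi-square per degree of freedom was 11.3 to 90.4, so no pair agreed within sampling noise.

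Totals were 74524410 to 77931045 counts per library in the HC human table, 68762301 to 69990709 in the HC chimpanzee table, 85595527 to 93003304 in the HO human table and 76437711 to 85616250 in the HO orangutan table. Contributor lines had 105052066 to 105282959 (human), 94421136 to 98702892 (chimpanzee) and 90854064 to 92585490 (orangutan). A count of 0 allows up to 3 counts, or 0.0403 CPM in the shallowest HC human library and 0.035 CPM in the shallowest HO human library, for counting error alone. Sequence alignments were not used here. Python 3.11.15, pandas 2.3.3, matplotlib 3.10.9 and Biostrings 2.70.1 were also used.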

Results

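Gene expression was measured in human-chimpanzee (HC) and human-orangutan (HO) fusion cells that carried either human mtDNA or the mtDNA of the ape contributor, and in the unfused human, chimpanzee and orangutan stem cells. The 7 groups are named HC_human_mt, HC_chimp_mt, HO_human_mt, HO_orang_mt, human_ESC, chimp_iPSC and orang_iPSC, with n = 3 libraries in each. Depth ran from 68762301 counts per library in the HC chimpanzee table to 105282959 in human_ESC. The series was designed to compare fusion cells with human mtDNA to fusion cells with ape mtDNA. Since the number of fused lines per group is not given, mtDNA type cannot be told apart from line or culture. An effect of mtDNA below means the difference between mtDNA groups.

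Transcripts of the 13 protein genes of mtDNA followed the mtDNA that the labels assign. They took 3.92% ± 0.38 (SD, n = 3) of human-table counts in HC_human_mt and 0.0469% ± 0.0064 in HC_chimp_mt, and 7.70% ± 0.88 in HO_human_mt against 0.000751% ± 0.000192 in HO_orang_mt. In the chimpanzee table the share was 0.994% ± 0.126 in HC_chimp_mt and 0.0327% ± 0.0031 in HC_human_mt. In the orangutan table it was 0.704% ± 0.042 in HO_orang_mt and 0.000139% ± 3.65e-05 in HO_human_mt. Among contributors the share was 5.62% ± 0.19 in human_ESC, 1.67% ± 0.11 in chimp_iPSC and 1.01% ± 0.11 in orang_iPSC. Relative to the contributor of its mtDNA the share was 0.697 times as large in HC_human_mt, 0.595 times in HC_chimp_mt and 0.695 times in HO_orang_mt, and 1.37 times as large in HO_human_mt. The groups did not overlap in any of these 8 comparisons, for each of which the exact permutation p was 0.10, the smallest that 3 against 3 libraries can give, and 0.10 after adjustment.

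Single mtDNA genes mostly went the way of the total. Relative to the contributor, 11 of 13 were lower in HC_human_mt with a median ratio of 0.705, 8 of 13 were lower in HC_chimp_mt with a median ratio of 0.735, and 12 of 13 were lower in HO_orang_mt with a median ratio of 0.735. In HO_human_mt 11 of 13 were higher, with a median ratio of 1.38.

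**Figure D1:**
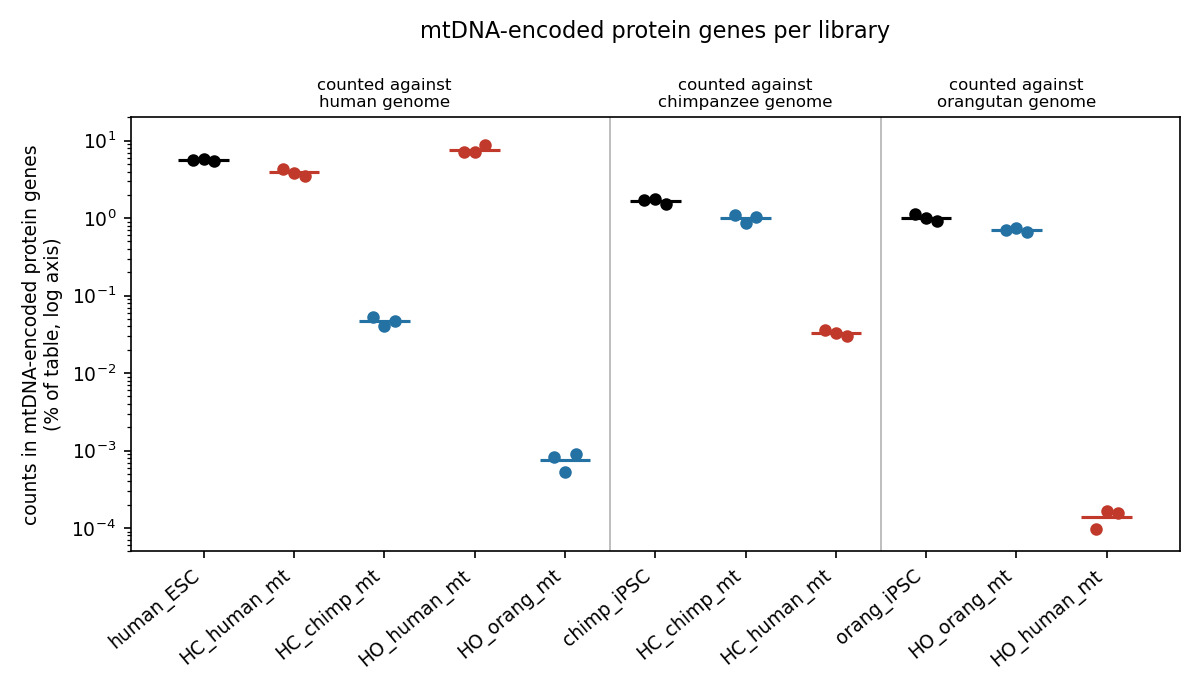
Share of counts in mtDNA-encoded protein genes (percent of the table, log axis) for each library, with points for the 3 libraries of a group and a line at their mean, arranged by the genome that reads were counted against. Composite groups that carry human mtDNA lie at 3.92% and 7.70% in human tables, and those that carry ape mtDNA at 0.0469% and 0.000751%.

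HC cells with chimpanzee mtDNA had lower transcripts of the integrated stress response than HC cells with human mtDNA. The transcription factor ATF4 drives this program when amino acids run short or mitochondria are impaired. In the human table TRIB3, a pseudokinase induced by this response, fell by 1.49 on the log2 scale (SE 0.19, adjusted p = 0.0093), from 35.8 ± 6.9 CPM (SD, n = 3) in HC_human_mt to 12.8 ± 3.3 in HC_chimp_mt. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell by 1.10 (SE 0.14, adjusted p = 0.0087), SLC7A11, the cystine transporter, by 1.05 (SE 0.13, adjusted p = 0.0080) and PSPH, the last enzyme of serine synthesis, by 0.59 (SE 0.06, adjusted p = 0.0031). INHBE, an inhibin beta subunit gene outside that list, fell by 1.54 (SE 0.26, adjusted p = 0.031), from 86.9 ± 11.6 to 29.9 ± 13.6 CPM. These genes lie at chromosome 20, 362835 to 397559 (TRIB3), chromosome 14, 24094053 to 24110598 (PCK2), chromosome 4, 138164097 to 138242349 (SLC7A11), chromosome 7, 56011051 to 56051604 (PSPH), and chromosome 12, 57452323 to 57459280 (INHBE), all on GRCh38 and protein-coding.

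Of 39 stress response members 17 fell and 0 rose in the human table, with 35 lower when adjusted over the list alone and a median log2 change of -0.56. The chimpanzee table gave 29 lower and 0 higher, 35 lower when adjusted over the list alone, and a median of -0.53. By camera the adjusted p was 1.9e-19 and 1.2e-19, and with an estimated correlation the adjusted p = 0.44 and 0.53. By fry it was 0.045 and 0.047. DESeq2 called 30 members lower in each table, and 0 higher. Each count moved with single libraries. In the human table it was 4 without HC_human_mt replicate 1 and 1 without HC_human_mt replicate 2. Without HC_chimp_mt replicates 1, 2 and 3 it was 3, 4 and 29. It was 0 without the expression filter and 2 with replicate number as a block. With all 12 composite libraries in 1 fit it was 8, and for symbols of both tables it was 31. In the chimpanzee table it was 16, 13, 12 and 15 without HC_human_mt replicate 1, HC_human_mt replicate 2, HC_chimp_mt replicate 1 and HC_chimp_mt replicate 2, and 3 without the filter.

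**Figure D2:**
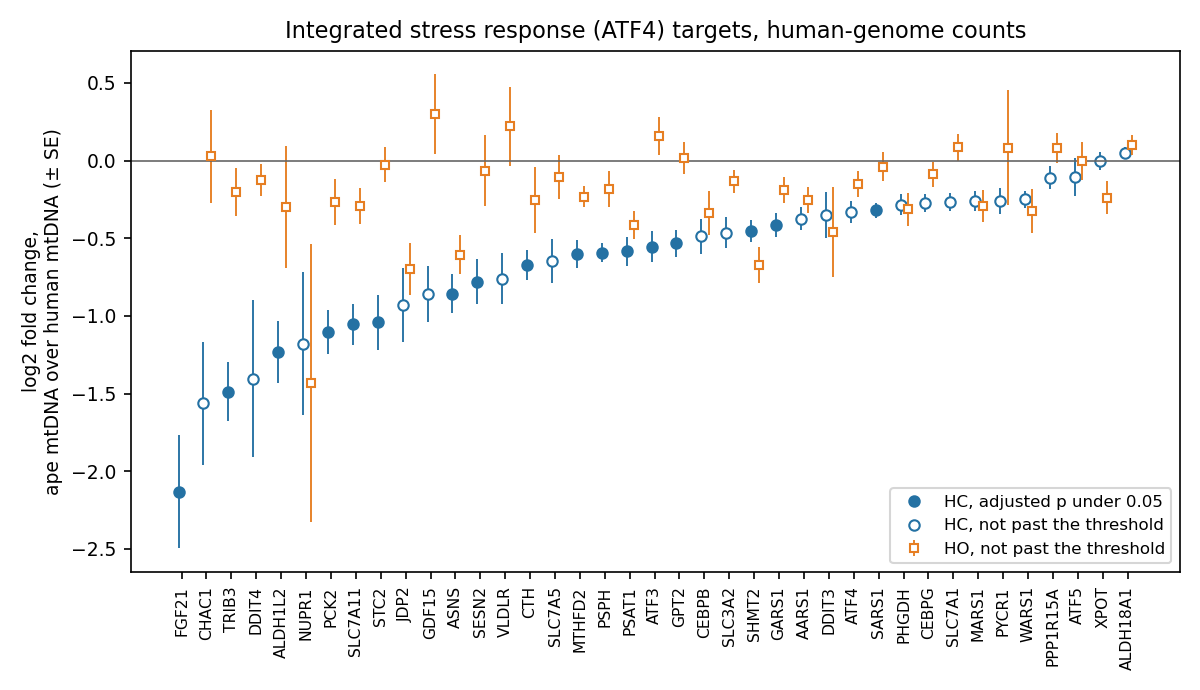
Log2 fold change with ape over human mtDNA (± SE, n = 3 per group) for each tested target of the integrated stress response in human-table counts, with blue circles for the HC fusion (filled where adjusted p was under 0.05) and orange squares for the HO fusion. In HC 17 of 39 targets passed the threshold, all lower, and in HO 0 of 38 passed by edgeR (10 at an unadjusted p under 0.05, 4 called by DESeq2).

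With chimpanzee mtDNA the interferon-induced membrane proteins IFITM1 (-0.47, SE 0.08, adjusted p = 0.032) and IFITM3 (-0.37, SE 0.07, adjusted p = 0.045) were also lower in the human table. The cell cycle inhibitor CDKN1A fell by 0.40 (SE 0.06) and PMAIP1, a pro-apoptotic BCL2 family gene, by 0.62 (SE 0.07). KDR, a VEGF receptor, fell by 0.41 (SE 0.08) and RPS4X, a ribosomal protein on chromosome X, by 0.30 (SE 0.05). EDA2R, a receptor of the TNF receptor family and p53 target on chromosome X (66595637 to 66639298), rose by 1.18 (SE 0.09, adjusted p = 0.00053), from 4.81 ± 0.08 to 10.9 ± 0.5 CPM. OTX2, a transcription factor of primed pluripotency and early brain, rose by 0.42 (SE 0.08), KRT7 by 0.43 (SE 0.08), PPRC1, a coactivator of mitochondrial gene programs, by 0.26 (SE 0.05) and the protocadherin PCDHGA10 by 0.59 (SE 0.06). Zinc finger genes went both ways, with ZNF558 (0.97, SE 0.14) and ZNF229 (0.90, SE 0.15) higher and ZNF528 (-3.74, SE 0.25) and ZNF248 (-1.40, SE 0.15) lower, all at means below 5 CPM. POU5F1 (-0.02, SE 0.05), SOX2 (0.06, SE 0.05), NANOG (-0.21, SE 0.05, adjusted p = 0.096) and the mtDNA packaging factor TFAM (0.08, SE 0.08) did not pass.

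In total 326 of 22598 nuclear genes passed in the human table, 110 higher and 216 lower with chimpanzee mtDNA. Among them 20 were nuclear copies of mtDNA, which include the largest changes, such as MTCO1P53 (12.32, SE 0.20), MTCO1P2 (12.10, SE 0.19), MTND4P24 (11.12, SE 0.27), MTCO1P40 (8.01, SE 0.14), MTND5P11 (7.76, SE 0.18), MTATP6P1 (-8.20, SE 0.16), MTND2P28 (-3.16, SE 0.19) and MTCO1P12 (-2.55, SE 0.12). Such copies may share reads with mtDNA, which differs between the groups by design, so their values are uncertain. The total was 113 and 84 without HC_human_mt replicates 1 and 2, 96, 110 and 632 without HC_chimp_mt replicates 1, 2 and 3, 1235 by DESeq2 (HC human genome), 44 without the filter, 90 with all 12 composite libraries in 1 fit and 525 for symbols of both tables. It was lower too with replicate number as a block, as given below under the dependence on processing.

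Other lists in the human table were called by camera too. Of 28 interferon response genes 2 fell, with 8 lower when adjusted over the list alone (median -0.23, camera adjusted p = 0.00011, adjusted p = 0.44 with an estimated correlation). Clustered protocadherins, which give neurons surface identity, had 1 of 56 higher, 2 adjusted over the list alone (median 0.27, camera adjusted p = 0.0014, adjusted p = 0.62 with an estimated correlation). Of 560 zinc finger genes 6 rose and 3 fell, with 10 and 5 adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.72 with an estimated correlation). Of 27 antioxidant (NRF2) targets 1 fell (SLC7A11, also a stress response target), 2 adjusted over the list alone (median -0.06, camera adjusted p = 0.027, adjusted p = 0.44 with an estimated correlation). Of 21 mesoderm markers 1 fell, 2 adjusted over the list alone (median -0.19, camera adjusted p = 0.027, adjusted p = 0.44 with an estimated correlation). Of 79 cytosolic ribosomal proteins 1 fell, 1 adjusted over the list alone (median -0.04, camera adjusted p = 0.019, adjusted p = 0.66 with an estimated correlation).

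Of 26 p53 targets 1 rose and 2 fell, with 1 and 6 adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.72 with an estimated correlation). Naive pluripotency genes (0 of 14 called by edgeR, 1 lower adjusted over the list alone, 4 at an unadjusted p under 0.05, 2 by DESeq2) had a median of -0.41 (camera adjusted p = 0.0026, adjusted p = 0.44 with an estimated correlation). Cholesterol synthesis genes (0 of 25 by edgeR, 3 higher and 1 lower adjusted over the list alone, 6 at an unadjusted p under 0.05, 4 by DESeq2) had a median of 0.10 (camera adjusted p = 0.013, adjusted p = 0.44 with an estimated correlation). Nuclear subunits of respiratory complexes I to V had 0 of 81 called by edgeR, 9 at an unadjusted p under 0.05 and 3 by DESeq2.

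The chimpanzee table, which comes from the same libraries, had 580 of 17971 genes past the threshold, 185 higher and 395 lower with chimpanzee mtDNA. FEZF1, a forebrain transcription factor, rose by 1.82 (SE 0.21, adjusted p = 0.0013), HEPH, a ferroxidase of iron export, by 1.21 (SE 0.08), EDA2R by 1.12 (SE 0.09) and SLITRK4, a neuronal membrane protein, by 1.10 (SE 0.10). TRIB3 fell by 1.59 (SE 0.19), CHAC1, which degrades glutathione, by 1.57 (SE 0.35, adjusted p = 0.036), INHBE by 1.53 (SE 0.23), SESN2, a stress-induced inhibitor of mTORC1, by 0.92 (SE 0.15) and the cystathionine lyase CTH by 0.69 (SE 0.09). Lower too were the glycolytic enzyme PKM (-0.40, SE 0.08), VEGFA (-0.58, SE 0.12), the neuronal tubulin TUBB3 (-0.33, SE 0.07), the anti-apoptotic BCL2L1 (-0.36, SE 0.05), and DPPA2 (-0.85, SE 0.17), while ACAT2 (0.22, SE 0.05) and UQCC3, an assembly factor of complex III (0.37, SE 0.09), were higher. MTRNR2L14 (5.68, SE 0.12) and MTRNR2L8 (-8.42, SE 0.26) resemble mitochondrial rRNA and are uncertain for the same reason as the copies above. Among 14233 symbols of both tables, 239 were called in the human table and 517 in the chimpanzee table, 217 in both, all 217 in the same direction. The total was 194, 176, 145, 165 and 895 without HC_human_mt replicates 1 and 2 and HC_chimp_mt replicates 1, 2 and 3, 1152 by DESeq2 (HC chimp genome) and 101 without the filter.

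In the HO fusion, few genes passed the threshold between the groups with orangutan and human mtDNA. In human-table counts, 9 of 23050 passed, and 7 of these were nuclear copies of mtDNA, among them MTATP6P1 (-13.02, SE 0.27), MTND2P28 (-12.56, SE 0.23), MTCO1P12 (-8.73, SE 0.10) and MTND4P12 (-8.51, SE 0.35). The remaining 2 had no symbol. In orangutan-table counts, 24 of 16811 passed, of which 23 rose and had no symbol, and SYT1, the calcium sensor of synaptic vesicle release, fell by 1.40 (SE 0.17, adjusted p = 0.031), from 44.3 ± 8.1 to 16.8 ± 2.9 CPM. Unnamed mtDNA genes of the orangutan table could not be left out, so the 23 may include such genes and were not read as nuclear changes. SYT1 lies on chromosome 12, had a change of -1.21 (adjusted p = 0.028) with chromosome shifts removed, and did not pass with symbols of both tables (adjusted p = 0.45) or without the filter (adjusted p = 0.050), nor without any 1 HO library other than HO_human_mt replicate 3 (adjusted p = 0.065 to 0.18). POU5F1 (-0.11, SE 0.09), SOX2 (0.10, SE 0.14), NANOG (-0.46, SE 0.26) and TFAM (-0.07, SE 0.13) did not pass in the human table. NANOG differed between libraries of 1 group, at 193, 155 and 83.9 CPM in HO_human_mt against 103, 107 and 105 in HO_orang_mt. It lies on chromosome 12, whose median shifts, given below, were smaller than this spread.

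In HO 29 of 38 stress response targets in human-table counts and 27 of 35 in orangutan-table counts were below zero, and none passed by edgeR. SHMT2, the mitochondrial serine hydroxymethyltransferase, had a log2 change of -0.68 (SE 0.12, adjusted p = 0.41) and ASNS, asparagine synthetase, of -0.61 (SE 0.12, adjusted p = 0.46), both named after their values were seen, and SHMT2 lies on chromosome 12. By edgeR 0 of 38 members passed in the human table, with 10 at an unadjusted p under 0.05, 4 by DESeq2 and 4 lower when adjusted over the list alone. The median was -0.19 (camera adjusted p = 0.00039, adjusted p = 0.66 with an estimated correlation), but -0.12 without HO_orang_mt replicate 1, -0.11 for the 24 members outside chromosomes 1, 12, 14 and 22, and -0.15 (30 of 38 below zero) with the chromosome shift of each library removed. In orangutan-table counts, 0 of 35 passed by edgeR, with 10 at an unadjusted p under 0.05, 3 by DESeq2 and 3 lower when adjusted over the list alone (median -0.20, camera adjusted p = 6.3e-05, adjusted p = 0.55 with an estimated correlation). Endoderm markers had a median of -0.59 in the human table (0 of 19 by edgeR, 0 adjusted over the list alone, 7 at an unadjusted p under 0.05, 1 by DESeq2, camera adjusted p = 0.011, adjusted p = 0.66 with an estimated correlation). For p53 targets it was 0.20 (0 of 26 by edgeR, 0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by DESeq2, camera adjusted p = 0.00047, adjusted p = 0.76 with an estimated correlation).

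Replicates of the HO groups spread more widely than those of HC, with a biological coefficient of variation of 0.252 in the HO human table against 0.136 in the HC human table. Without HO_human_mt replicate 3 the counts were 63 in the human table and 156 in the orangutan table, and DESeq2 called 220 and 152. The human-table count was 56 with all 12 composite libraries in 1 fit, 49 with mtDNA genes kept in and 0 by edgeR for symbols of both tables, where the orangutan-table count was 0 too (1114 at an unadjusted p under 0.05 for HO human genome and 1058 for HO orangutan genome). Chromosome-wide shifts also set single HO libraries apart. Relative to the mean of the fusion, genes of chromosome 12 had a median shift of 0.23 (log2) in HO_human_mt replicate 1 and 0.18 in replicate 2 against -0.11 in replicate 3. Genes of chromosomes 1 and 14 had a shift of 0.20 and 0.17 in HO_orang_mt replicate 1, and those of chromosome 22 of 0.17 in HO_human_mt replicate 1. Chromosome X stood at 0.10, 0.09 and -0.06 in HO_human_mt replicates 1, 2 and 3. All chromosomes of the HC human table lay between -0.07 and 0.05.

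**Figure D3:**
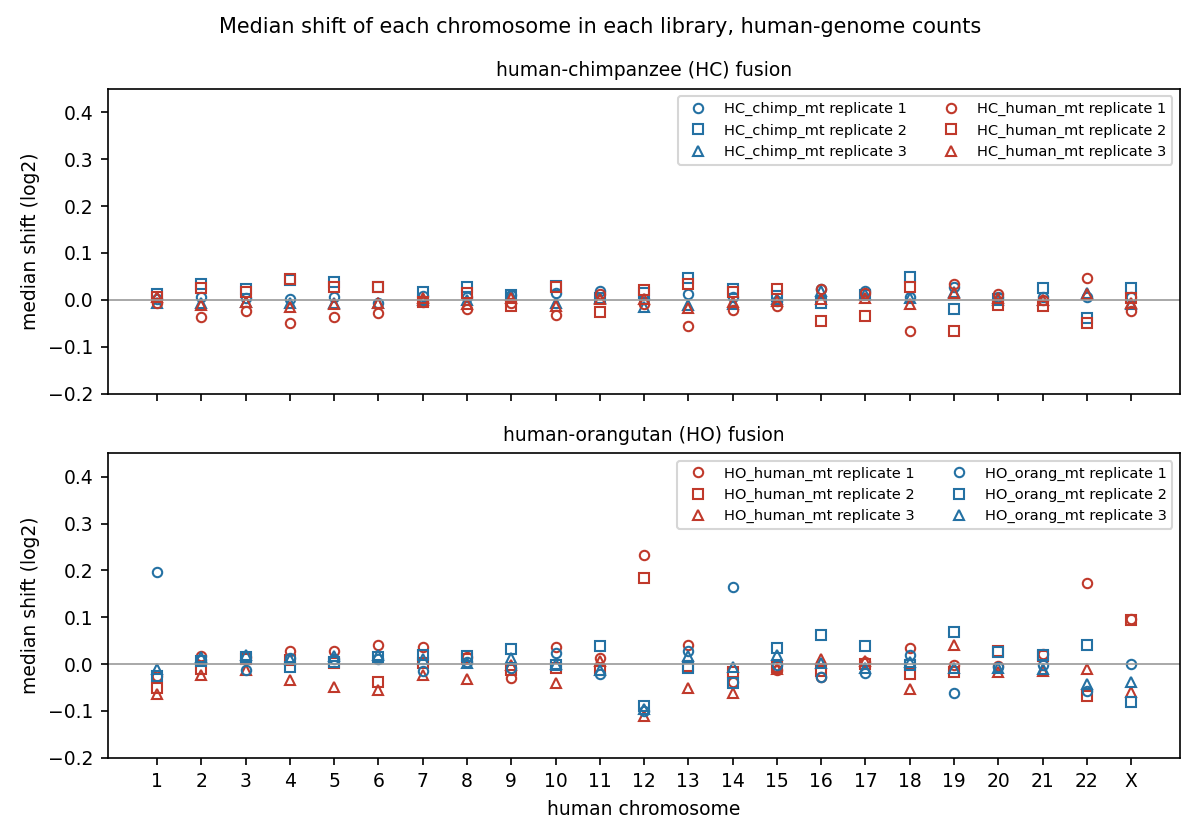
Median shift (log2, relative to the mean of the 6 libraries) of the genes on each human chromosome in each library of the HC and HO fusions, from human-table counts, with red for human mtDNA and blue for ape mtDNA and a symbol per replicate. Chromosome 12 reaches 0.23 and 0.18 in HO_human_mt replicates 1 and 2, and in HC every chromosome lies between -0.07 and 0.05.

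Summing both tables put the mtDNA genes beside the nuclear ones. In HC 12 of 13 mtDNA-encoded protein genes were lower with chimpanzee mtDNA, led by MT-ATP6 (-6.86, SE 0.14), MT-ATP8 (-5.72, SE 0.14) and MT-CO3 (-3.83, SE 0.10), while MT-ND1 (-0.32, SE 0.09, adjusted p = 0.063) did not pass by edgeR, and DESeq2 called 13 of 13 lower. In HO all 13 were lower with orangutan mtDNA, from MT-CO2 (-2.08, SE 0.08) to MT-ND4L (-12.47, SE 0.14). Adjusted over the list alone, 13 of 13 were lower in each fusion (camera adjusted p = 1.1e-22 and 2.2e-60, and adjusted p = 0.42 and 0.088 with an estimated correlation). The share of these genes differed between the contributors' own tables, at 5.62%, 1.67% and 1.01%. MT-ATP6, MT-ATP8 and MT-CO3 had 9.57, 5.06 and 211 CPM (here without TMM scaling) in chimp_iPSC against 4053, 489 and 9146 in human_ESC. MT-CO2 and MT-ND4L had 1560 and 0.368 CPM in orang_iPSC against 5571 and 1294 in human_ESC. Gaps in these genes thus also lie between unfused lines, and were not read as lower expression with ape mtDNA in the fusions. How far each gap reflects expression or the recovery of mtDNA reads in each table was not separated. Over all genes 738 of 15030 passed in HC (227 higher, 511 lower) and 13 of 14424 in HO, all of mtDNA. The HC total was 288 and 312 without HC_human_mt replicates 1 and 2, and 194, 266 and 1163 without HC_chimp_mt replicates 1, 2 and 3. In HO it was 153 without HO_human_mt replicate 3.

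Whether the difference between mtDNA groups varied between the 2 fusions was tested as an interaction. It was past the threshold for 38 of 25113 genes, 14 of them nuclear copies of mtDNA and 6 without a symbol. EDNRB, the endothelin receptor of neural crest, differed by 8.36 (HO minus HC, SE 0.66, adjusted p = 0.00010): it stood at 8.28, 7.55 and 8.58 CPM in HC_human_mt and at 0, 0.067 and 0 in HC_chimp_mt, against 73.4, 60.1 and 105 in HO_human_mt and 49.7, 85.0 and 96.5 in HO_orang_mt. HLA-DQB1, a class II antigen presentation gene, differed by 2.54 (SE 0.42, adjusted p = 0.047) and FA2H, a fatty acid hydroxylase of myelin lipids, by 2.11 (SE 0.31, adjusted p = 0.020). Neither passed within HO, and within the HC human table HLA-DQB1 fell by 1.23 (SE 0.09, adjusted p = 0.00033) and FA2H did not pass (-0.71, SE 0.15, adjusted p = 0.059). The count was 23 without HC_human_mt replicate 3, 24 and 70 without HC_chimp_mt replicates 1 and 3, 631 without HO_human_mt replicate 3 and 340 by DESeq2 (mtDNA effect HO minus HC, human genome). The stress response list had a median difference of 0.33 (0 of 39 by edgeR, 10 higher adjusted over the list alone, 16 at an unadjusted p under 0.05, 5 by DESeq2, camera adjusted p = 3.7e-08, adjusted p = 0.74 with an estimated correlation). Across 11215 genes the mtDNA effects of HC and HO had a Pearson r of 0.097 and a Spearman rho of 0.081, where genes are not independent replicates. The fusions shared 7 called genes, 5 in the same direction, where independent lists would share 0.0088 higher and 0.060 lower, and 1 once nuclear copies of mtDNA were left out, which went in opposite directions in the fusions.

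The ratio of human-table to ape-table counts shifted with mtDNA for 1 symbol in each fusion. TMEM185B, a transmembrane protein gene, had a log2 ratio of 3.30 ± 0.07 in HC_chimp_mt and 1.44 ± 0.08 in HC_human_mt, a difference of 1.87 (SE 0.06, adjusted p = 0.00047, 1 of 14812 symbols). Its chimpanzee-table counts fell by 1.88 (SE 0.10) while its human-table counts did not pass (0.02, SE 0.07, adjusted p = 0.92). SYT1 had a log2 ratio of 0.95 ± 0.07 in HO_orang_mt and -0.06 ± 0.03 in HO_human_mt, a difference of 1.01 (SE 0.04, adjusted p = 0.0014, 1 of 14266 symbols). The HC count was 2 without HC_human_mt replicate 2 and 2 without HC_chimp_mt replicate 2, and 6 by DESeq2. The HO count was 3 and 2 without HO_human_mt replicates 1 and 3, and 8 by DESeq2. Human tables held 51.885% ± 0.041 of nuclear counts in HC_human_mt and 51.858% ± 0.028 in HC_chimp_mt (exact p = 0.50), and 52.164% ± 0.043 in HO_human_mt against 50.69% ± 0.15 in HO_orang_mt (exact p = 0.10). With symbols of both tables only, the order turned in both fusions, at 51.519% in HC_human_mt against 51.589% in HC_chimp_mt and 51.373% in HO_human_mt against 51.43% in HO_orang_mt. Since it is not known whether the tables are split by allele, these ratios were not read as allele usage.

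Against the human contributor, HC_human_mt had higher stress response targets and lower core pluripotency genes. PYCR1, a proline synthesis enzyme and stress response target, rose by 1.61 (SE 0.09, adjusted p = 1.5e-06), and the metallothionein genes MT1H, MT1G and MT1F, which bind metals, fell by 9.09 (SE 0.32), 8.45 (SE 0.20) and 7.47 (SE 0.17). NODAL, a ligand that sustains primed pluripotency, fell by 4.35 (SE 0.14), and PCDHB5 (-1.79, SE 0.09), ZNF229 (-3.07, SE 0.13) and SOX2 (-0.23, SE 0.07) were lower, while the pseudogene ADAMTS7P4 rose by 10.72 (SE 0.27). In all 12634 of 23472 genes passed, 6488 higher and 6146 lower. Of 39 stress response targets 31 rose and 1 fell, with 32 and 1 adjusted over the list alone (median 0.77, camera adjusted p = 7.8e-07, adjusted p = 0.98 with an estimated correlation). Of 30 core pluripotency genes 3 rose and 20 fell, with 5 and 20 adjusted over the list alone (median -0.65, camera adjusted p = 0.00014, adjusted p = 0.42 with an estimated correlation). Of 57 protocadherins 9 rose and 29 fell, with 10 and 29 adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.53 with an estimated correlation). In this and the next 3 comparisons species content and table differ along with fusion. Ploidy may differ too, since only the composite samples are labelled tetraploid.

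Against the same contributor, HO_human_mt had higher p53 targets and higher markers of mesoderm, trophoblast and naive pluripotency. GADD45A, a DNA damage response gene, rose by 2.25 (SE 0.11), TWIST1, a mesoderm transcription factor, by 5.49 (SE 0.23), MVK, mevalonate kinase, by 2.31 (SE 0.16) and NANOG by 1.10 (SE 0.26, adjusted p = 0.011). SOX2 (-0.28, SE 0.08), GPAT2 (-5.46, SE 0.41), MIAT (-4.03, SE 0.41) and RAB4B-EGLN2 (-6.60, SE 1.5) fell, and NMRAL2P (12.85, SE 0.99), PPIAP6 (10.21, SE 0.28) and LINC02484 (9.90, SE 0.62) rose. In all 9846 of 23709 genes passed, 5327 higher and 4519 lower. Of 26 p53 targets 21 rose and 0 fell, 21 adjusted over the list alone (median 0.88, camera adjusted p = 1.0e-05, adjusted p = 0.96 with an estimated correlation). Of 26 mesoderm markers 19 rose and 0 fell, 20 and 1 adjusted over the list alone (median 2.70, camera adjusted p = 6.7e-05, adjusted p = 0.54 with an estimated correlation). Of 16 trophoblast and amnion markers 11 rose and 1 fell, 12 and 1 adjusted over the list alone (median 1.75, camera adjusted p = 0.0021, adjusted p = 0.54 with an estimated correlation). Of 17 endoderm markers 10 rose and 3 fell, 11 and 4 adjusted over the list alone, without a list call (camera adjusted p = 0.10, adjusted p = 0.87 with an estimated correlation). Of 15 naive pluripotency genes 11 rose and 0 fell, 12 adjusted over the list alone (median 1.43, camera adjusted p = 0.00064, adjusted p = 0.90 with an estimated correlation). Of 25 cholesterol synthesis genes 17 rose and 1 fell, the same adjusted over the list alone (median 0.56, camera adjusted p = 0.00014, adjusted p = 0.90 with an estimated correlation).

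Against the chimpanzee contributor, HC_chimp_mt had lower cholesterol synthesis and histone transcripts. ACAT2, an acetyl-CoA acetyltransferase, fell by 1.48 (SE 0.05), and H2BC12 (-2.82, SE 0.10), the potassium channel KCNN4 (-4.06, SE 0.09), MT1X (-3.73, SE 0.38) and BRINP2 (-3.48, SE 0.14) were lower too. ZFP42, a pluripotency marker, rose by 10.17 (SE 0.17), from 0.061 ± 0.026 to 71.8 ± 8.7 CPM, and the stress factor ATF3 by 2.33 (SE 0.10). NANOG fell by 0.62 (SE 0.05), SOX2 by 0.49 (SE 0.04) and POU5F1 by 0.18 (SE 0.05). In all 12561 of 18086 genes passed, 6488 higher and 6073 lower. Of 25 cholesterol synthesis genes 2 rose and 23 fell, the same adjusted over the list alone (median -0.74, camera adjusted p = 7.0e-07, adjusted p = 0.54 with an estimated correlation). Of 45 histone genes 6 rose and 26 fell, with 7 and 26 adjusted over the list alone (median -1.10, camera adjusted p = 0.0015, adjusted p = 0.54 with an estimated correlation). Of 38 stress response targets 30 rose and 3 fell, the same adjusted over the list alone (median 0.47, camera adjusted p = 0.0015, adjusted p = 0.74 with an estimated correlation).

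Against the orangutan contributor, HO_orang_mt had higher p53 targets, naive pluripotency genes and trophoblast markers. AEN, a p53-induced nuclease, rose by 1.45 (SE 0.05), KLF5, a factor of naive pluripotency and trophoblast, by 3.99 (SE 0.15), ANXA1 by 8.55 (SE 0.21), RGS5 by 8.82 (SE 0.49), AADACL3 by 9.77 (SE 0.52) and TFAM by 0.20 (SE 0.07, adjusted p = 0.032). LHX2, a forebrain transcription factor, fell by 5.19 (SE 0.21), ISLR by 5.53 (SE 0.22), the neuroendocrine granin CHGA by 4.70 (SE 0.25) and H2BC11 by 2.09 (SE 0.08). In all 11152 of 16950 genes passed, 5717 higher and 5435 lower. Of 22 p53 targets all 22 rose, 22 adjusted over the list alone (median 1.60, camera adjusted p = 1.3e-08, adjusted p = 0.54 with an estimated correlation). Of 13 naive pluripotency genes 11 rose and 0 fell, 12 adjusted over the list alone (median 3.48, camera adjusted p = 9.7e-05, adjusted p = 0.30 with an estimated correlation). Of 14 trophoblast and amnion markers 13 rose and 0 fell, 13 adjusted over the list alone (median 2.81, camera adjusted p = 0.00021, adjusted p = 0.54 with an estimated correlation).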

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

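Of the tests in this part, those of ape mtDNA of either species and of mtDNA type were chosen after the result was seen.

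The effect of mtDNA differed between the fusions for 38 genes by an interaction test, and by camera with a preset correlation for 10 gene lists, of which 0 held with an estimated correlation and 0 by fry. Among called genes with a symbol and a mean of at least 5 CPM, EDNRB had the largest positive difference (HO minus HC), 8.36, followed by HLA-DQB1 with 2.54 and FA2H with 2.11. Nuclear copies of mtDNA stood at the other end, with -11.56 for MTND4P12, -11.26 for MTND5P11 and -11.16 for MTND4P24. With other splits of the libraries into groups, 3 of 100 (the real one included) gave as many calls, and the highest other gave 409. That split, and the one with 352, set HO_human_mt replicates 1 and 2 and HO_orang_mt replicate 1 against the other 3 HO libraries and kept the HC libraries in their mtDNA groups. The same HO grouping with mixed HC groups gave at most 10, so these counts go with the HC mtDNA groups together with a structure of the HO samples that is not mtDNA. All other drawn splits that kept the HC mtDNA groups and mixed the HO libraries gave 21 to 29. Counts of that size thus arise without the HO mtDNA grouping. The share of 3 in 100 therefore does not by itself show an interaction.

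For the lower stress response targets with chimpanzee mtDNA, the least negative median without 1 library was -0.47. A single library therefore does not account for the shift. Over other scalings, filters and tools the least negative median was -0.52. Filters and tools hardly act on a median of log2 changes, so this value cannot decide how far they account for the calls. Members called lower in human-table counts were 17 by the main fit, 17 with DESeq2 size factors and 30 by DESeq2. They numbered 0 without the expression filter, 2 with replicate number as a block and 8 with all 12 composite libraries fitted together. An effect that ape mtDNA of either species might have stays open, because the HO median was -0.19 in the human table (-0.12 without HO_orang_mt replicate 1, -0.11 for the 24 of 38 members outside the 4 shifted chromosomes, -0.15 with chromosome shifts removed) and no member passed there by edgeR (10 at an unadjusted p under 0.05, 4 by DESeq2). In splits of the HC libraries into 3 against 3, of which there are 10, the real one had 17 members lower in the human table and 29 in the chimpanzee table, the highest other had 0, and the real split was the only 1 to reach its count. These are too few splits for a share under 0.05.

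Chromosome-wide shifts in HO libraries were weighed likewise. Removing each library's trend on GC content left at least 94.2% of every shift, and HO_human_mt replicate 3 had a chromosome 12 shift of -0.11 although it carries the same mtDNA as replicates 1 and 2, so neither GC content nor mtDNA type accounts for them. An extra copy of chromosome 12 in replicates 1 and 2 fits, since 10 of 10 bins along it had a gap over 0.1. Its gaps ran from 0.19 to 0.37. With 1 extra copy in a fused cell that holds 4, the gap would be 0.32 if human-table counts cover all 4 copies. Whether they do was not settled, so the size of the gaps cannot decide this. In HO_orang_mt replicate 1 the gap passed 0.1 in 10 of 10 bins on chromosome 1 and 9 of 10 on chromosome 14. In HO_human_mt replicate 1 it did in 10 of 10 on chromosome 22. These chromosomes and libraries were picked for their shift, so the bins show only that it spans the chromosome. Copy number was not measured.

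Nuclear copies of mtDNA were weighed as reads of mtDNA counted at those copies. Of 6 copies lower with orangutan mtDNA, 6 had a human_ESC mean within 4-fold of HO_human_mt, and of 14 copies higher with chimpanzee mtDNA, 12 had a human_ESC mean under 1/16 of HC_chimp_mt. Both fit that explanation. The human_ESC group shares human mtDNA and the human nuclear copies with HO_human_mt, and lacks chimpanzee mtDNA. Transcription of the copies that followed mtDNA type would therefore meet both criteria too, and these tests cannot tell the explanations apart. No biological explanation was tested.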

How the results depend on the processing

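The tests of leaving out nuclear copies of mtDNA, leaving out 4 chromosomes and removing chromosome shifts were chosen after the result was seen. Of 255 values that answer a comparison, 178 stayed the same, 77 moved and 0 reversed, with the human share counted for each group by itself and not as a difference. Counts of genes or lists called have no direction, so they could not reverse. Of 2456 values of named genes, 2161 stayed the same, 256 became weaker, 11 stronger, 28 moved and 0 reversed. The cause was not tested unless stated. DESeq2 called 1235 genes (HC human genome), 1152 (HC chimp genome), 220 (HO human genome), 152 (HO orangutan genome), 1391 (HC combined, the summed tables), 142 (HO combined), 340 (mtDNA effect HO minus HC, human genome, the interaction), and 6 and 8 for the ratios of tables (HC allele by mtDNA and HO allele by mtDNA). Without an expression filter the HC counts were 44 (human), 101 (chimpanzee) and 481 (summed), with more genes tested. With replicate number as a block the HC human count was 87, and 2 stress response targets were lower there instead of 17. Correlations of libraries with the same number were -0.09, 0.24 and 0.03 (HC human) and -0.02, 0.28 and -0.07 (HC chimpanzee). They were 0.24, -0.19 and 0.17 (HO human) and 0.35, -0.22 and 0.17 (HO orangutan). Over all pairs correlations ran from -0.28 to 0.31, -0.33 to 0.31, -0.31 to 0.24 and -0.40 to 0.44 in the same order. So few correlations cannot decide whether numbers pair the samples. With all 12 composite libraries fitted together the counts were 90 (HC human) and 56 (HO human). With symbols of both tables only they were 525 (HC human), 0 (HO human) and 0 (HO orangutan). Keeping mtDNA genes in gave 49 in the HO human table, and leaving them out gave 0 in summed HO tables. Leaving out nuclear copies of mtDNA gave 1 (HO human), 17 (interaction) and 1 gene shared by the fusions, and leaving out chromosomes 1, 12, 14 and 22 gave 3 (HO human). Without 1 library counts ran from 84 to 632 (HC human), 145 to 895 (HC chimpanzee), 7 to 63 (HO human), 19 to 156 (HO orangutan), 194 to 1163 (HC summed), 13 to 153 (HO summed), 23 to 631 (interaction), 1 to 2 (HC ratio) and 1 to 3 (HO ratio). Against contributors they ran from 10815 to 12692 (HC_human_mt), 7016 to 11196 (HO_human_mt), 11602 to 12106 (HC_chimp_mt) and 9879 to 11611 (HO_orang_mt). Lists called by camera numbered 12 (HC human), 13 (HC chimpanzee), 11 (HO human), 12 (HO orangutan), 11 (HC summed), 14 (HO summed), 10 (interaction), 6 (HC_human_mt against human_ESC), 9 (HO_human_mt against human_ESC), 7 (HC_chimp_mt against chimp_iPSC) and 9 (HO_orang_mt against orang_iPSC). With an estimated correlation each of these was 0, and by fry they were 7, 5, 0, 0, 6, 1, 0, 15, 9, 21 and 22. Without the 10 most abundant nuclear genes 2 shares moved (mtDNA-encoded share of counts: HO_orang_mt, table HO_orangutan, to 0.763%, and mtDNA-encoded share of counts: human_ESC, table Hcontrol, to 5.90%). With symbols of both tables the human share was 51.519% (HC_human_mt), 51.589% (HC_chimp_mt), 51.373% (HO_human_mt) and 51.43% (HO_orang_mt), so the order of the groups turned in both fusions.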

Other observations

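The tests in this part other than splits of the libraries were chosen after the result was seen.

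X-linked genes were called more often than autosomal ones between HC_chimp_mt and HC_human_mt. In human-table counts, 29 of 466 passed (6.22%) against 178 of 11557 autosomal genes (1.54%), with a Fisher exact p of 1.7e-09. In chimpanzee-table counts, 33 of 355 passed (9.30%) against 3.52% of autosomal genes (exact p = 1.1e-06). Both EDA2R and HEPH, which rose, and RPS4X, which fell, are X-linked. Genes are not independent replicates, so these p-values overstate the evidence.

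Among HO_human_mt libraries, GDF3 and histone transcripts varied, while POU5F1 (302 ± 24 CPM) and SOX2 (228 ± 11 CPM) varied less. GDF3 lies on chromosome 12, which was shifted by 0.23, 0.18 and -0.11 in replicates 1, 2 and 3, and POU5F1 and SOX2 lie on other chromosomes. GDF3, a TGF-beta ligand of pluripotent cells, stood at 106.4, 115 and 19.5 CPM in HO_human_mt replicates 1, 2 and 3 and at 27.2, 27.1 and 32.1 in HO_orang_mt. This spread is larger than the median shift of its chromosome. Histone genes deviated from the mean of the fusion by 0.01, 0.91 and -0.45 (median, log2) in HO_human_mt and by 0.22, -0.35 and -0.35 in HO_orang_mt. GDF3 and the histone list were chosen after their values were seen.

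Other splits of the libraries gave these values, where 10 splits of 3 against 3 are too few for a share under 0.05. The real split called 326 genes in the HC human table and 580 in the HC chimpanzee table, with 3 and 2 in the highest other and 1 split, the real one, reaching each count. For summed HC tables it called 738, with 0 in the highest other and 1 split reaching it. In HO it called 9 in the human table (highest other 8, reached by 1 split), 24 in the orangutan table (highest other 81, reached by 2) and 13 in the summed tables (highest other 139, reached by 2). The splits with 81 and 139 again group HO_human_mt replicates 1 and 2 with HO_orang_mt replicate 1, a structure of the samples other than mtDNA. For the table ratios the real count was 1 in each fusion, reached by 6 splits in HC (highest other 2) and by 4 in HO (highest other 1). For the 4 comparisons with contributors the highest other split called 0, and 1 split reached the real count in each.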
